A study of Mus musculus with 11 samples.

How the data were processed

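Bulk RNA sequencing measured transcript levels in the hippocampus of mice at 14 months of age. The labels place the 11 libraries in 3 groups. There were 4 libraries of wild-type C57BL/6J mice (WT), 3 of APP/PS1 transgenic mice given sham exposure and 4 of APP/PS1 mice exposed to a rotating magnetic field (RMF) of 0.4 T. APP/PS1 mice carry a mutant transgene of the amyloid precursor protein, among others, and deposit amyloid plaques with age. Per the labels, exposure or sham exposure ran on 5 days per week for 12 months, for 3 h a day from 2 to 11 months of age and for 6 h a day from 11 to 14 months. The labels do not say whether the WT mice were handled in the same apparatus or were littermates. They also do not say that each library came from a separate animal, and the extraction protocol speaks of pooled RNA, so p-values measure the spread between these libraries, which may be partly technical. The labels give the tissue as hippocampus and the cell type as neurons. No step that would isolate neurons is recorded, and the libraries are treated here as whole hippocampal tissue.

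Per the labels' protocols, libraries were made from 5 µg of total RNA with oligo(dT) beads, sequenced as paired reads of 150 bp on an Illumina instrument, and trimmed with Cutadapt 1.9. The submitters' processing notes name HISAT2 2.0.4, StringTie 1.3.4d and edgeR. They also name a human genome build, whereas the gene identifiers in the table are those of mouse genes, so the mouse build is not given in the sources used here and coordinates are printed as the table gives them. The authors deposited whole-number counts per gene and library, not normalized, and FPKM values beside them. The deposited FPKM values were rescaled counts: the ratio of count to FPKM, taken relative to each library's scale, had a coefficient of variation under 1% for 99.6% of 14926 genes checked, with a median of 0.188%. The counting tool, its handling of reads that match several genes and its use of strand are not given in the sources used here. Values of overlapping or antisense genes, pseudogenes and members of families with near-identical copies, such as Mup, Serpina1 and H2 genes, are therefore uncertain. The table also held 2 columns of values whose name matched no sample, and these were not used.

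The table lists 36826 genes, and library totals lay between 68124548 and 70786786 counts. Counts from replicates were compared in pairs, and every pair differed by more than sampling noise (chi-square per degree of freedom between 14.9 and 211). No replicate therefore repeated the counts of another, and each library was counted as 1 replicate. The comparison cannot tell libraries of separate animals from separate preparations of 1 RNA pool. Levels are given as CPM, which is the count of a gene relative to the library's counts on all tested genes, scaled by TMM, with the SD over the libraries of a group. Intervals and floors cover counting error only.

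Genes with an FPKM of at least 1 in at least 3 libraries were tested, which left 14428 genes. The design fixed before the data were examined named limma on log2 FPKM for a table holding FPKM alone and edgeR's quasi-likelihood test if whole-number counts were present. Counts were present, so edgeR's test (edgeR 4.0.16, R 4.3.3) was used, with all 11 libraries in 1 fit of 3 groups and no covariate. Every adjusted p of a single gene is from this test with Benjamini-Hochberg adjustment over all genes tested, and the threshold was 0.05. SE values are of the log2 difference, derived from the test's F statistic. A fold against a group with no counts is a lower bound computed against 3 counts over the group. A ratio against a group with 1 to 3 counts is given with its 95% counting interval.

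Gene lists were fixed with the design, as 28 lists of pathways and 20 lists of cell-type or tissue markers, of which 47 had at least 3 tested members. The list of perivascular macrophage markers had 1 of 7 members tested and was not tested. Lists were tested with camera of limma 3.58.1, which asks whether the members of a list lie higher or lower than other genes, with its preset correlation between genes of 0.01. Its adjusted p is over the 47 lists within a comparison. The test was repeated with a correlation estimated for each list, and with fry, which asks whether the members move on balance in 1 direction. In 18 list tests the median, the mean and the test differed in sign, and 0 of these passed the threshold. Scores of a list per library are mean log2 deviations of its members from their mean over libraries, and were compared between groups with two-sided exact permutation tests. A test of transcript length, chosen after the lists had been seen, took lengths from the ratio of counts to FPKM, removed the smoothed trend of each library's log2 CPM values with length, and ran camera on log2 CPM values before and after, so its values differ from those of the count fit.

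The genes named in the text were chosen by a rule fixed with the design. It takes transgene-related genes, of which App and Prnp are reported here, up to 12 genes with the largest rise and 12 with the largest fall among genes past the threshold whose groups do not overlap and whose symbol is not a predicted name, the 10 genes of smallest p where fewer than 5 pass, and up to 4 members of smallest p from each list described. Genes named outside this rule are said to be so where they appear. Lists of 12 other organs were written after the genes past the threshold had been seen.

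The count test was checked on simulated counts drawn at the real means and library sizes, with 100 genes changed by 1.5-fold and 100 by 2-fold among 14428. For sham against WT it recovered 27% of the former and 74% of the latter, with 2 false calls. For RMF against sham it recovered 21% and 67%, with 2 false calls, and for RMF against WT 38% and 68%, with 4. In the simulation of RMF against sham, a list of 20 genes raised by 1.5-fold passed the list test of limma, and 1 of 100 unchanged lists had an unadjusted p below 0.05. Genes were drawn independently of each other there. That check therefore does not cover correlated lists, and in the data the estimated correlation was 0.425 for oxidative phosphorylation genes.

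Alternatives covered DESeq2 1.42.0 with its own size factors, limma on log2(FPKM + pseudocount) with pseudocounts of 1 and 0.1, other filters on low values, other scalings, library weights, a fit of the compared groups only, the replicate number as a block, other thresholds, and leaving out each library in turn. Sex was not used as a covariate, since all 11 libraries held Y-linked transcripts. Expected values under shared libraries came from 20 simulations of unchanged groups, and from 10 simulations with equal sham and RMF groups.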

Results

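The data were counts of transcripts in hippocampal tissue of 4 WT, 3 APP/PS1 sham and 4 APP/PS1 RMF libraries at 14 months of age. Library totals ranged from 68124548 counts in sham replicate 4 to 70786786 in RMF replicate 3, and between 26789 and 27388 genes had at least 1 count. For the median gene, the 95% confidence interval of a log2 difference reached 0.31 to either side for sham against WT and for RMF against sham, and 0.28 for RMF against WT. Transcripts encoded by mitochondria took 9.53% of counts in sham 4 and between 5.76% and 7.39% in the other libraries. The first principal component separated WT from both APP/PS1 groups, and sham and RMF libraries lay together. WT 3 lay apart from the other WT libraries, with a median correlation to its own group of 0.956 against 0.975 to 0.986 for the other 10 libraries. Its score for markers of dentate granule cells was -1.64, against 0.09 to 0.58 in the other WT libraries, and its score for neocortex markers was 1.23, against -0.29 to 0.02.

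**Figure D1:**
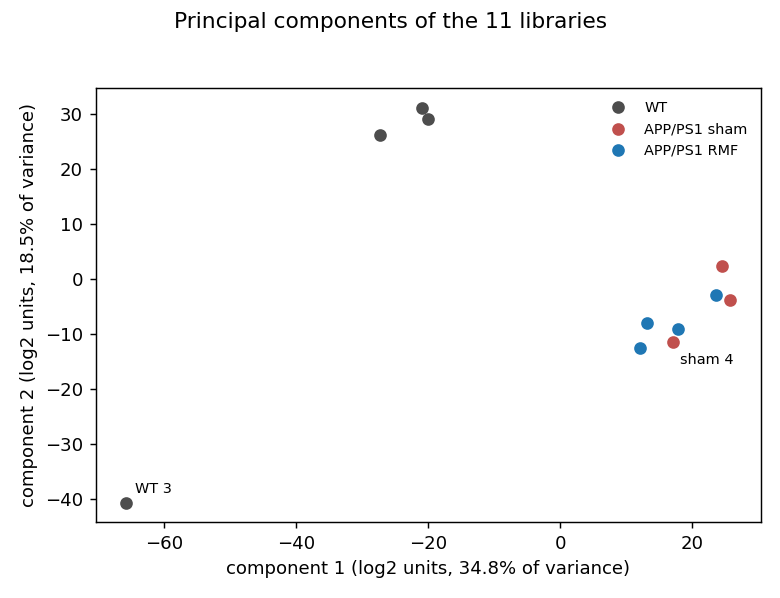
Each point is 1 library, placed by its scores (log2 units) on the first principal component, which holds 34.8% of the variance, and the second, which holds 18.5%. All 7 APP/PS1 libraries lie between 12.1 and 25.8 on component 1 and the 4 WT libraries between -65.8 and -20.1, with WT 3 the farthest.

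The comparison of APP/PS1 sham with WT asks what differs in the transgenic hippocampus without field exposure. App, which encodes the amyloid precursor protein (ENSMUSG00000022892, chromosome 16, 84746573 to 84970654), stood at 3417 ± 396 CPM (SD, n = 3) in sham and 1592 ± 32.5 CPM (n = 4) in WT, a 2.15-fold rise (log2 difference 1.10, SE 0.0871, adjusted p = 0.000116). Prnp, which encodes the prion protein and whose promoter drives both transgenes in a widely used APP/PS1 line (ENSMUSG00000079037, chromosome 2, 131751848 to 131780349), rose 2.25-fold from 613 ± 57.8 to 1382 ± 152 CPM (adjusted p = 0.000127). Lamr1-ps1, a processed pseudogene that the table places just upstream of Prnp on chromosome 2 (131746006 to 131746879), rose from 0.0324 ± 0.0475 to 7.77 ± 1.03 CPM (adjusted p = 5.99e-05), with a WT mean of 0.00968 CPM without WT 4. In the list of 3 transgene-related genes, 2 rose, App and Prnp, and 2 also adjusted over the list alone. The list passed the test (adjusted p = 6.02e-17, and adjusted p = 0.00177 with an estimated correlation).

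Microglial genes that are known to be induced around amyloid plaques were higher in sham than in WT. Itgax, which encodes the integrin CD11c, rose 18.0-fold from 0.384 ± 0.164 to 6.95 ± 2.52 CPM, and Cst7, which encodes the cysteine protease inhibitor cystatin F, rose 28.3-fold from 0.465 ± 0.499 to 13.3 ± 5.63 CPM, and 60.6-fold without WT 3, which held 1.21 CPM. Clec7a, the beta-glucan receptor dectin-1, rose 11.7-fold (adjusted p = 0.000477), the chemokine Ccl6 rose 3.65-fold (adjusted p = 0.00143), and Trem2, a lipid-sensing receptor of microglia, rose 2.36-fold from 10.02 ± 1.49 to 23.7 ± 6.21 CPM (adjusted p = 0.00333). Of 23 measured members of the plaque-associated microglia list, 10 rose and 0 fell, with 16 higher and 1 lower adjusted over the list alone, and the list passed the test (adjusted p = 2.47e-30, and 0.0107 with an estimated correlation). Of 14 measured genes of homeostatic microglia, Selplg, a selectin ligand, rose 1.42-fold (adjusted p = 0.0292) and 0 fell, with 10 higher adjusted over the list alone. Csf1r and Cx3cr1 stood at 1.40- and 1.35-fold of WT with adjusted p of 0.0692 and 0.102. That list passed camera with the preset correlation (adjusted p = 1.85e-08, against adjusted p = 0.173 with an estimated correlation) and also passed by fry (adjusted p = 0.0213). Among 10 measured general markers of microglia and macrophages, 4 rose, namely Laptm5, Fcgr3, C1qa and Ly86, by 2.02-, 1.77-, 1.79- and 1.85-fold, with 9 higher adjusted over the list alone (list adjusted p = 4.71e-19, and adjusted p = 0.0165 with an estimated correlation).

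Complement genes were higher in sham as well. C3, the central component of the cascade, which the liver also makes in quantity, rose 6.79-fold from 2.39 ± 0.658 to 16.2 ± 2.64 CPM (adjusted p = 6.2e-05), its receptor gene C3ar1 rose 3.47-fold, C1qa 1.79-fold and the integrin gene Itgb2 2.04-fold. In the complement list 5 of 12 measured members rose and 10 were higher adjusted over the list alone (adjusted p = 1.09e-23, and adjusted p = 0.00918 with an estimated correlation). Lysosomal genes rose in 4 of 20 cases, 13 adjusted over the list alone, with Laptm5, Grn, Ctss and Hexa at 2.02-, 1.43-, 1.67- and 1.41-fold (list adjusted p = 3.3e-11, and adjusted p = 0.0436 with an estimated correlation). In the reactive astrocyte list, Osmr, a subunit of the oncostatin M receptor, rose 2.32-fold and Vim, an intermediate filament gene, 1.56-fold, 2 of 13 measured members and 5 adjusted over the list alone (adjusted p = 2.22e-06, and adjusted p = 0.0161 with an estimated correlation). Gfap, the main astrocyte filament gene, stood at 756 ± 184 CPM in sham and 267 ± 119 in WT, where WT 3 was lowest at 92.1 CPM, and did not pass (2.84-fold, adjusted p = 0.0821).

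Other lists passed camera with the preset correlation and not with an estimated one. By fry, the antigen presentation, cytokine and NF-kB, cholesterol synthesis, and pericyte and smooth muscle lists passed as well (adjusted p = 0.0246, 0.000914, 0.00592 and 0.0106). The interferon response, unfolded protein response and heat shock lists did not pass by fry (adjusted p = 0.0634, 0.131 and 0.102). For antigen presentation, 2 of 9 measured members rose, 4 adjusted over the list alone, with the class I genes H2-K1 and B2m at 1.58- and 1.49-fold. The list passed with the preset value (adjusted p = 8.66e-06, against adjusted p = 0.173 with an estimated correlation). For the interferon response, 0 of 15 passed by edgeR and 3 were higher adjusted over the list alone (adjusted p = 0.000769, against adjusted p = 0.37 with an estimated correlation). In the cytokine and NF-kB list the receptor genes Tlr7 and Tlr2 rose 2.24- and 2.28-fold, 2 of 11 measured and 3 adjusted over the list alone (adjusted p = 0.00153, against adjusted p = 0.0518 with an estimated correlation). For cholesterol synthesis, Sqle and Hmgcs1 rose 1.42- and 1.31-fold, 2 of 16 measured and 7 adjusted over the list alone, and all 16 lay above WT (adjusted p = 1.74e-08, against adjusted p = 0.132 with an estimated correlation). The chaperone gene Calr in the unfolded protein response list rose 1.23-fold (1 of 18 measured, 4 adjusted over the list alone, adjusted p = 0.0247 and adjusted p = 0.451 with an estimated correlation). The co-chaperone gene Bag3 in the heat shock list rose 1.52-fold (1 of 13, 1 adjusted over the list alone, adjusted p = 0.0145 and adjusted p = 0.451 with an estimated correlation). Smooth muscle genes of the pericyte and smooth muscle list rose, with Acta2, Tagln and Myh11 at 3.54-, 3.63- and 2.98-fold, 3 of 8 measured and 3 adjusted over the list alone (adjusted p = 7.09e-08, against adjusted p = 0.113 with an estimated correlation). The call of the unfolded protein response list ended without WT 1, WT 2, sham 1 or sham 3 (adjusted p = 0.056, 0.123, 0.258 and 0.144) and that of the heat shock list without WT 2 or sham 1 (adjusted p = 0.0615 and 0.444). The difference in score of the former, 0.13, was 0.07, 0.08 and 0.24 without sham 1, sham 3 and sham 4, and that of the latter, 0.28, was 0.08 without sham 1 and 0.45 without sham 4.

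Lower in sham than in WT by the list test were nuclear genes of oxidative phosphorylation and immediate early genes. For oxidative phosphorylation 0 of 29 members passed singly by edgeR and 8 were lower adjusted over the list alone, and 0 of 29 lay above WT, with a median log2 difference of -0.27 (adjusted p = 3.39e-10, against adjusted p = 0.278 with an estimated correlation). By fry the oxidative phosphorylation list passed and the immediate early list did not (adjusted p = 0.0338 and 0.559). Sham 4, the library with the largest mitochondrial share, had the lowest score of the list, -0.43, against -0.05 and -0.10 in the other sham libraries, and without it the difference in score from WT went from -0.29 to -0.17 (adjusted p = 5.14e-06). Across genes, log2 differences of sham from WT rose with transcript length (Spearman correlation 0.239, against -0.206 for RMF from sham). The median length was 2221 bases in this list and 4211 over tested genes. Removal of the length trend was not tested for sham against WT. For immediate early genes, which neurons induce within minutes of activity, 0 of 20 passed and 0 adjusted over the list alone (adjusted p = 0.0284, against adjusted p = 0.771 with an estimated correlation). WT 3 had a score of 1.49 for these genes against -0.41 to 0.06 in the other WT libraries, and without WT 3 and sham 4 the direction of the list turned (adjusted p = 0.783). The call ended without WT 3, sham 3 or sham 4 alone (adjusted p = 0.97, 0.317 and 0.121), and the difference in score, -0.43, was -0.02 without WT 3, -0.25 without sham 3 and -0.66 without WT 1.

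Apart from Lamr1-ps1, most of the largest rises and falls between sham and WT were in genes known from other organs. Lypd8 and Dmbt1, made by intestinal epithelium, Scgb1a1, the secretoglobin of airway club cells, and Mup22 and Mup11, urinary protein genes of the liver, had 0 counts in all 4 WT libraries and were at least 1038-, 882-, 424-, 367- and 216-fold higher in sham, with Lypd8 at 11.2 ± 0.884 CPM. Single libraries carried part of these bounds, which were 271 for Scgb1a1 without sham 4, and 175 for Mup22 and 141 for Mup11 without sham 1. Agr2, Sval1 and Mptx1 also had 0 counts in WT and were at least 185-, 75.2- and 72.9-fold higher. Kap, an androgen-regulated kidney gene, rose from 0.0144 ± 0.0287 to 9.09 ± 1.47 CPM, Krt19 from 0.0142 to 4.32 CPM and Zg16 from 0.0181 to 3.64 CPM, with all WT counts of these 3 genes in WT 4, WT 3 and WT 1, respectively. The 12 falls included genes of fast skeletal muscle fibres, with the calcium pump gene Atp2a1 at 11.3 ± 1.96 CPM in WT and 0.253 ± 0.022 in sham, Myh4 at 16.4 and 0.546, Tnnt3 at 5.97 and 0.0682, Ckm at 5.08 and 0.177, Tnni2 at 2.29 and 0.27, Actn3 at 3.84 and 0.677, Myl1 at 2.55 and 0.615 and Acta1 at 11.5 and 2.78 CPM. All sham counts of Tnnt3 were in sham 4. Tnnc2 had 0 counts in sham and was at least 120-fold lower than in WT, or 79.1- and 79.2-fold without sham 1 and without sham 3. Outside muscle, Slc30a3, the zinc transporter of synaptic vesicles, fell to 0.734-fold (83.2 ± 5.73 against 61.0 ± 4.58 CPM, adjusted p = 0.0336) and Ift27, an intraflagellar transport gene, to 0.584-fold (adjusted p = 0.0437).

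Organ lists written after these genes were seen gave summed levels that separated the genotypes. The 20 liver genes summed to between 1.86 and 22.6 CPM in WT libraries and to between 120 and 412 CPM in APP/PS1 libraries, with means of 12.6 ± 9.70 in WT, 312 ± 86.5 in sham and 150 ± 53.1 in RMF. Alb, the liver albumin gene, stood at 7.59 ± 6.53, 172 ± 41.2 and 69.5 ± 26.7 CPM. Large intestine genes summed to 7.89, 87.9 and 65.2 CPM in WT, sham and RMF, kidney genes to 4.28, 27.8 and 30.4, lung genes to 1.14, 14.8 and 13.7, and smooth muscle genes to 26.4, 67.9 and 63.8. Skeletal muscle genes summed to 109 ± 19.97 CPM in WT, 36.1 ± 5.90 in sham and 37.6 ± 2.71 in RMF. Most of the skeletal muscle sum in APP/PS1 libraries was Pvalb, Ttn and Neb, with 965, 602 and 408 counts in sham 1. Summed levels of the heart, pancreas, testis, skin, stomach, and thymus and spleen lists overlapped between the genotypes, with heart means of 472, 497 and 453 CPM, pancreas 1.76, 2.03 and 2.77, testis 11.5, 11.4 and 11.3, skin 15.8, 13.4 and 15.5, stomach 3.77, 2.23 and 2.94, and thymus and spleen 4.28 (2.07 without WT 3), 4.46 and 3.57. The heart sums were almost all Ryr2 (27744 to 35290 counts per library), which is also on the calcium handling list. The testis sums were mostly Hspa1l (670 to 949 counts). The heart and testis sums therefore say little about RNA of those organs. Of the 122 genes higher in sham, 37 were on an organ list, and of the 12 lower, 9. On the 7 lists of microglia, complement, antigen presentation, lysosome and cytokine genes, which were fixed with the design, were 26 of the 122. The counts of 37 and 26 cannot be compared, since the organ lists were written after the calls were seen. The organ lists also hold Acta2, Tagln and Myh11, which are on the pericyte and smooth muscle list.

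**Figure D2:**
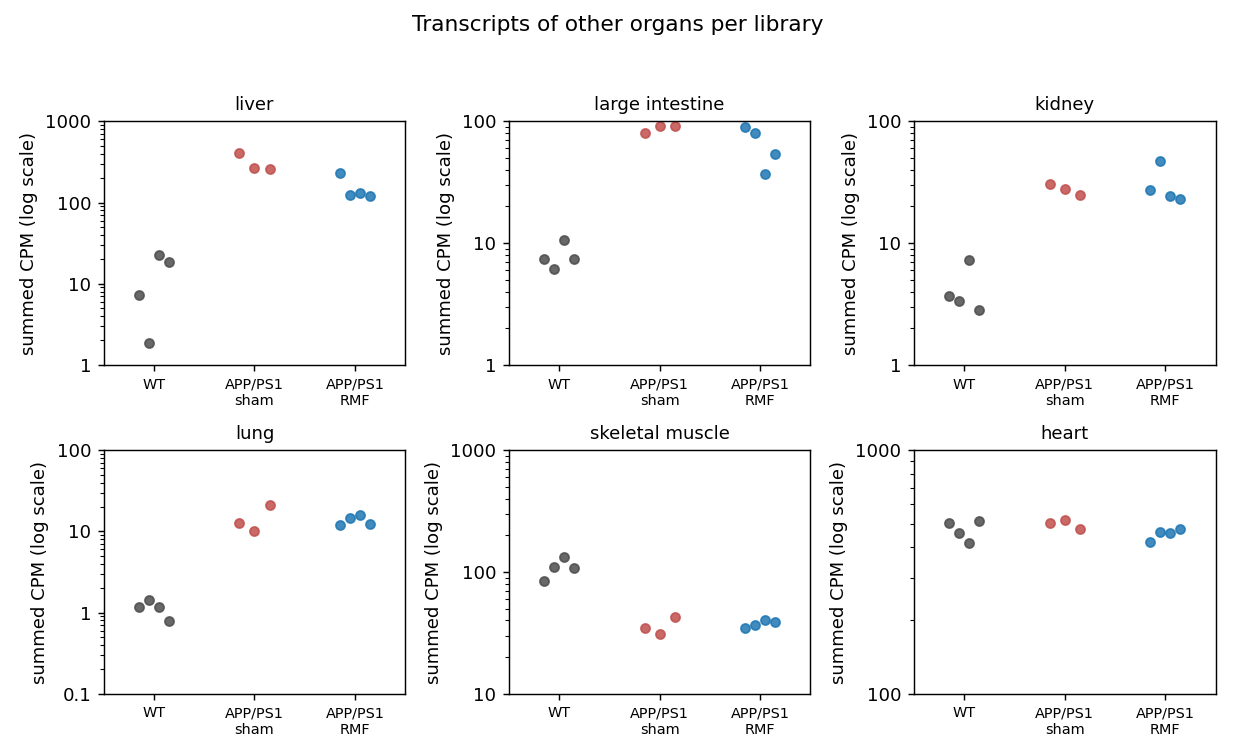
Each point is the summed level of 1 organ list in 1 library, in CPM on a log scale, by group. Liver sums lie between 1.86 and 22.6 in WT and between 120 and 412 in APP/PS1 libraries, skeletal muscle sums lie higher in WT, and heart sums, which are almost all Ryr2, overlap.

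In all, edgeR called 134 of 14428 genes in sham against WT, 122 higher and 12 lower, of which 114 and 11 differed by at least 1.5-fold. An unadjusted p below 0.05 was found for 1907 genes, where chance gives 721, and 12.7% of all genes tested had groups that did not overlap, where chance gives 5.71%. Other splits of the sham and WT libraries gave 2322 such genes (WT 2, WT 3 and sham 4 against the rest) and 1927 (WT 1, WT 3 and WT 4 against the rest). Chance therefore cannot be excluded for the 1907. Of the 47 lists 16 passed with the preset correlation, 6 of them with an estimated correlation and 12 of them by fry. By fry the autophagy list also passed, downward (adjusted p = 0.0387 by fry, against 0.341 by camera). The number of genes was 71 without genes on the organ lists, 76 with only the sham and WT libraries fitted, 87 with the replicate number as a block, 89 without sham 3, 215 at an adjusted p below 0.1, 252 with library weights, 304 without a filter on low values, 345 by DESeq2 (251 higher and 94 lower) and 363 with a minimum FPKM of 0.1. Leaving out 1 library ended the calls of Ift27, B2m, Bag3, Calr, Ly86, Slc30a3, Selplg, Hexa, Sqle, Myh4, Hmgcs1, Itgb2, Vim, Tlr2, H2-K1, Tlr7, Ctss, Mptx1 and Tnnc2, with adjusted p reaching 0.21 for Ly86 without sham 3 and 0.181 for Ift27 without sham 4.

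The comparison of APP/PS1 RMF with APP/PS1 sham asks what 12 months of field exposure changed in the transgenic hippocampus. By edgeR 0 of 14428 genes passed the threshold, with 994 at an unadjusted p below 0.05, where chance gives 721, and DESeq2 called 16. App stood at 3387 ± 159 CPM (n = 4) in RMF and 3417 ± 396 (n = 3) in sham (log2 difference -0.01, SE 0.0877) and Prnp at 1496 ± 39.3 and 1382 ± 152. Among plaque-associated microglial genes, Itgax stood at 7.54 ± 1.10 against 6.95 ± 2.52 CPM, Clec7a at 9.89 ± 0.851 against 10.5 ± 3.38, Cst7 at 16.2 ± 3.26 against 13.3 ± 5.63 and Trem2 at 30.8 ± 3.29 against 23.7 ± 6.21. C3 stood at 11.0 ± 0.990 against 16.2 ± 2.64 CPM, with the lowest sham library at 14.3 and the highest RMF library at 12.1 (0.678-fold, adjusted p = 0.719). The summed liver genes were also lower in RMF, between 120 and 230 CPM against 256 to 412 in sham, so C3 from liver RNA cannot be told apart here.

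The smallest adjusted p by edgeR was 0.719, shared by the 10 genes of smallest p. These did not pass by edgeR, and all 10 were among the 16 genes called by DESeq2. Slc8b1, which encodes the mitochondrial sodium and calcium exchanger, stood at 9.10 ± 0.627 CPM in RMF and 5.51 ± 0.968 in sham (1.65-fold), and Ndufa2, a subunit of respiratory complex I, at 7.09 ± 0.424 and 3.86 ± 0.351 (1.84-fold). The ribosomal protein gene Rpl39 stood at 1.75-fold and Gpld1, a phospholipase gene, at 1.23-fold of sham, while the neural adhesion gene Opcml stood at 0.800-fold and Ankrd29 at 0.738-fold. The pseudogenes Gm12428, Gm7664 and Gm15542, whose reads cannot be told from those of near-identical genes here, stood at 0.703-, 3.35- and 0.694-fold. A miscellaneous RNA without a symbol (ENSMUSG00002074930) had 3 counts over the sham group and 153 over RMF, a ratio of 36.9 with a counting interval of 12.4 to 181.

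Of the 47 lists 7 passed with the preset correlation, 0 with an estimated correlation and 0 by fry. In each of the 7 lists 0 members passed by edgeR, and over the list alone 2 of the oxidative phosphorylation genes were higher and 0 members passed in the other 6. Nuclear oxidative phosphorylation genes lay higher in RMF for 27 of 29 members, with a median log2 difference of 0.21 (adjusted p = 1e-11, against adjusted p = 0.888 with an estimated correlation). Their score was 0.05 ± 0.05 in RMF, -0.20 ± 0.20 in sham and 0.09 ± 0.09 in WT, and the exact permutation test of RMF against sham gave p = 0.0286, the smallest it can give, and 0.336 after adjustment over the lists. The calcium handling, oxidative stress and autophagy lists gave the same p and adjusted p, with differences in score of -0.11, 0.13 and 0.07. The plaque-associated microglia, presynaptic, postsynaptic and mitochondrially encoded lists gave p = 0.2, 0.114, 0.143 and 0.429 by the exact permutation test. Against WT the lowest adjusted p of the exact permutation test were 0.149 for sham and 0.0896 for RMF, with 9 and 15 lists at the smallest p of 0.0286. With this floor an adjusted p can fall below 0.05 only if many more of the 47 lists reach it at once. The lack of a list past the threshold after adjustment therefore decides nothing in any comparison. Without sham 4, which scored -0.43, the difference in score of oxidative phosphorylation genes went from 0.25 to 0.13 (adjusted p = 0.000133). Sdhb stood at 1.29-fold and Cox4i1 at 1.26-fold of sham. Presynaptic genes lay higher in RMF for 2 of 19 members, with a median log2 difference of -0.13 (adjusted p = 0.00261, against adjusted p = 0.888 with an estimated correlation). General neuron markers, some of them also on the presynaptic list, lay higher for 2 of 10, with a median of -0.14, and did not pass (adjusted p = 0.0696). Pclo, a scaffold gene of the active zone, stood at 379 ± 39.1 against 473 ± 58.2 CPM and the synapsin gene Syn1 at 409 ± 49.9 against 507 ± 66.0 CPM. Postsynaptic glutamate genes lay higher for 2 of 19, with Dlg2 at 0.863-fold and Shank1 at 0.861-fold (adjusted p = 0.00916, against adjusted p = 0.941 with an estimated correlation). Calcium handling genes did so for 3 of 22, with the channel gene Cacna1a at 0.840-fold (adjusted p = 0.0121, against adjusted p = 0.888 with an estimated correlation). Mitochondrially encoded genes lay higher for 2 of 13, with mt-Atp8 at 0.617-fold and mt-Nd3 at 1.23-fold (adjusted p = 0.00263, against adjusted p = 0.894 with an estimated correlation). Sham 4 had a score of 0.67 for that list, against -0.15 and -0.05 in the other sham libraries, and without it the direction turned (adjusted p = 0.722). Plaque-associated microglial genes lay higher for 17 of 23, with Cd52 at 1.95-fold and Fabp5 at 1.38-fold (adjusted p = 0.00787, against adjusted p = 0.888 with an estimated correlation). Fabp5 lay between 32.9 and 39.0 CPM in RMF, 22.2 and 30.0 in sham and 28.9 and 41.5 in WT. Its RMF values were thus within the WT range and not above it. Oxidative stress genes lay higher for 17 of 23, with Gpx4 at 1.29-fold and Prdx6 at 1.15-fold (adjusted p = 0.0356, against adjusted p = 0.888 with an estimated correlation).

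Of these 7 calls, that of oxidative phosphorylation genes was kept with each library left out in turn, and the others were not. Without sham 1 the adjusted p was 0.733 for plaque-associated microglial genes, 0.254 for postsynaptic and for calcium handling genes and 0.111 for oxidative stress genes. Without RMF 1 it was 0.118 for presynaptic, postsynaptic, calcium handling and oxidative stress genes, and without sham 4 it was 0.173 for oxidative stress genes. The difference in score of plaque-associated microglial genes, 0.20, was 0.10 without sham 1 and 0.33 without sham 3, and that of postsynaptic genes went from -0.12 to -0.08 without sham 1. That of presynaptic genes went from -0.11 to -0.07 without RMF 1, that of oxidative stress genes from 0.13 to 0.07 without sham 4, and that of mitochondrially encoded genes from -0.23 to -0.39 without sham 1 and to 0.02 without sham 4. The lists were also tested on log2 CPM values before and after the trend of each library with transcript length was removed. The calls of calcium handling, postsynaptic and plaque-associated microglial genes ended (adjusted p from 0.0226 to 0.511, from 0.022 to 0.302 and from 0.022 to 0.0762), and the median log2 difference of calcium handling genes went from -0.12 to -0.04. Medians of the postsynaptic and plaque-associated microglial lists went from -0.125 to -0.107 and from 0.175 to 0.146. Oxidative stress genes did not pass in this form before or after (adjusted p = 0.0617 and 0.216), and the other 3 lists passed in both.

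**Figure D3:**
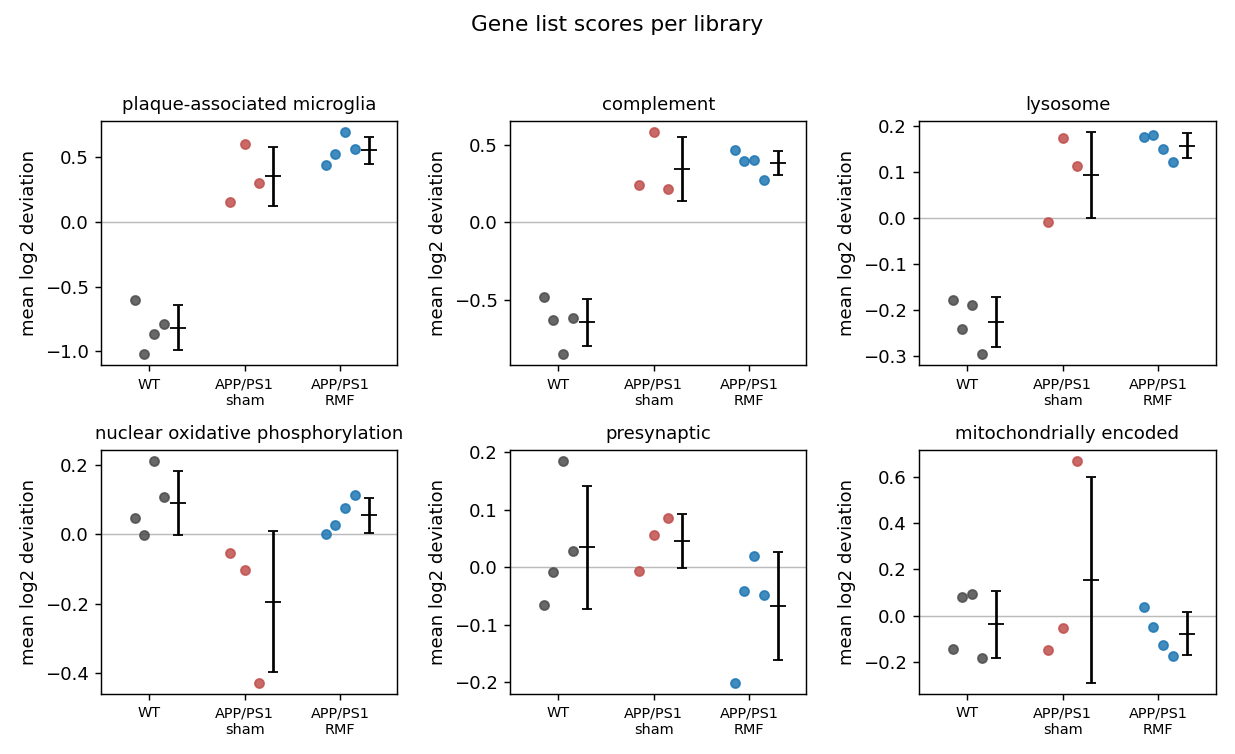
Each point is the mean log2 deviation of a list's members from their mean over the 11 libraries, for 1 library, with the group mean and SD beside the points. The plaque-associated microglia score was -0.82 in WT, 0.35 in sham and 0.56 in RMF, and the oxidative phosphorylation score was lowest in sham 4 at -0.43.

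Of the 16 genes called by DESeq2 12 were higher and 4 lower. Without sham 1 edgeR called 1 gene, Ppia, which encodes cyclophilin A and was chosen after its values were seen (adjusted p = 0.00369). It stood at 140 CPM in sham 3 and 162 in sham 4, against 444 in sham 1. The number of lists past the threshold with the preset correlation was 4 with library weights, 3 without sham 1 and without RMF 1, 11 without sham 4 and 13 without sham 3. The groups did not overlap for 10.6% of genes, where chance gives 5.71%.

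The comparison of APP/PS1 RMF with WT asks what differs from WT in the exposed transgenic hippocampus. App stood 2.13-fold and Prnp 2.44-fold above WT (adjusted p = 7.02e-05 and 4.47e-05). Itgax rose 19.5-fold to 7.54 ± 1.10 CPM (n = 4), Cst7 34.6-fold (74.1-fold without WT 3) to 16.2 ± 3.26, Clec7a 11.1-fold to 9.89 ± 0.851, Ccl6 4.49-fold to 7.25 ± 1.07 and Trem2 3.07-fold to 30.8 ± 3.29 CPM. Ctsd, a lysosomal protease gene, rose 2.04-fold from 269 ± 10.1 to 550 ± 32.8 CPM (adjusted p = 0.000392), Cd52 3.96-fold and Lgals3, which encodes galectin-3, 3.43-fold. In the plaque-associated microglia list 14 of 23 members rose and 0 fell, 17 higher adjusted over the list alone (adjusted p = 9.12e-58, and adjusted p = 0.00148 with an estimated correlation).

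**Figure D4:**
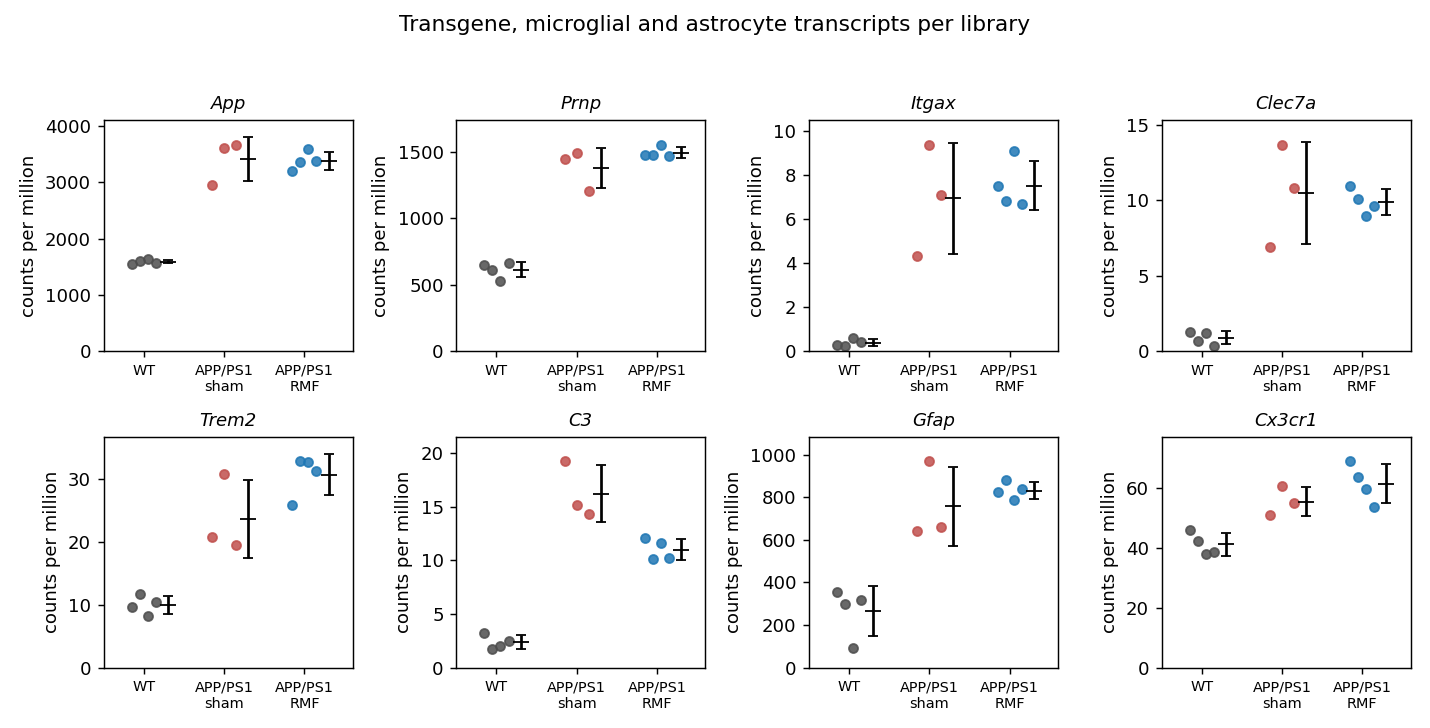
Each point is the level of 1 gene in 1 library, in CPM on a linear axis from 0, with the group mean and SD beside the points. App had a mean of 1592 in WT and at 3417 and 3387 in sham and RMF, Itgax at 0.384, 6.95 and 7.54, and Gfap was lowest in WT 3 at 92.1.

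Among homeostatic microglial genes Csf1r and the fractalkine receptor gene Cx3cr1 rose 1.52- and 1.49-fold. In this list 3 of 14 members rose, and 8 adjusted over the list alone (adjusted p = 3.97e-15, against adjusted p = 0.0559 with an estimated correlation). General microglia and macrophage markers rose in 8 of 10 cases, 10 adjusted over the list alone, with Fcgr3 and Laptm5 at 1.93- and 1.87-fold (adjusted p = 6.01e-31, and adjusted p = 0.00301 with an estimated correlation). Complement genes rose in 7 of 12 cases, 11 adjusted over the list alone, with C3 at 4.61-fold, C3ar1 at 3.49-fold and C1qb at 1.92-fold. That list passed in both forms (adjusted p = 3.13e-34, and adjusted p = 0.00164 with an estimated correlation). Lysosomal genes rose in 8 of 20 cases, 15 adjusted over the list alone, with Ctss at 1.87-fold and Ctsl at 1.46-fold (adjusted p = 1.88e-21, and adjusted p = 0.00521 with an estimated correlation). Reactive astrocyte genes rose in 4 of 13 cases, 5 adjusted over the list alone, with Vim, Osmr, Ggta1 and Gfap at 1.78-, 1.98-, 2.14- and 3.12-fold. The call of the list was kept (adjusted p = 1.41e-09, and adjusted p = 0.00301 with an estimated correlation). Tlr2 and Tlr7 rose 2.84- and 2.31-fold. They were 2 of 11 cytokine and NF-kB genes and 6 adjusted over the list alone (adjusted p = 6.51e-07, and adjusted p = 0.00521 with an estimated correlation). The transgene-related list again had 2 of 3 members higher, 2 adjusted over the list alone (adjusted p = 1.65e-22, and adjusted p = 0.000694 with an estimated correlation).

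Of the oxidative stress list, Cybb, Cyba and Ncf1, which encode subunits of the phagocyte NADPH oxidase, rose 4.91-, 2.27- and 1.82-fold and the peroxiredoxin gene Prdx6 1.25-fold. This made 4 of 23 members and 5 adjusted over the list alone (adjusted p = 0.000369, against adjusted p = 0.0716 with an estimated correlation). H2-K1 and H2-D1 rose 1.54- and 1.60-fold. They made up 2 of 9 antigen presentation genes and 5 adjusted over the list alone (adjusted p = 1.39e-09, against adjusted p = 0.0559 with an estimated correlation). Trim30a rose 2.45-fold, 1 of 15 interferon response genes and 4 adjusted over the list alone (adjusted p = 1.12e-06, against adjusted p = 0.129 with an estimated correlation). Sqle rose 1.37-fold, 1 of 16 cholesterol synthesis genes and 6 adjusted over the list alone (adjusted p = 5.85e-09, against adjusted p = 0.0925 with an estimated correlation). Acta2, Tagln and Myh11 rose 3.44-, 3.59- and 2.69-fold. This was 3 of 8 pericyte and smooth muscle genes and 3 adjusted over the list alone (adjusted p = 2.13e-09, against adjusted p = 0.0585 with an estimated correlation). Astrocyte, oligodendrocyte and oligodendrocyte precursor markers passed the list test upward. In all 3 of them 0 members passed by edgeR and 0 adjusted over the list alone (adjusted p = 0.00149, 0.012 and 0.00426, against adjusted p = 0.182, 0.665 and 0.256 with an estimated correlation). In WT 3 the oligodendrocyte score was -1.20, against -0.53 to 0.55 in the other WT libraries. The unfolded protein response list also passed upward, with 0 members past the threshold and 2 adjusted over the list alone (adjusted p = 0.00728, against adjusted p = 0.293 with an estimated correlation). Immediate early and presynaptic genes passed downward with 0 of 20 and 0 of 19 members past the threshold. In both, 0 passed adjusted over the list alone (adjusted p = 0.00109 and 0.036, against adjusted p = 0.659 and 0.651 with an estimated correlation). Without WT 3, whose immediate early score was 1.49, the calls of the immediate early, presynaptic and oligodendrocyte lists ended (adjusted p = 0.817, 0.145 and 0.35), and their differences in score went from -0.44 to -0.03, from -0.10 to -0.05 and from 0.50 to 0.20. The presynaptic and oligodendrocyte calls also ended without WT 4 (0.0614 and 0.0659) and without RMF 1 (0.364 and 0.368, with differences in score of -0.06 and 0.25), and that of the unfolded protein response without WT 2 (0.0631). Without WT 1 the differences of the immediate early and oligodendrocyte lists were -0.66 and 0.79.

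Most of the largest rises and falls were again in genes known from other organs. Lypd8, Dmbt1, Scgb1a1, Mup22, Mup11, Agr2, Mptx1 and Sval1, with 0 counts in WT, were at least 823-, 557-, 432-, 182-, 163-, 126-, 109- and 46.8-fold higher in RMF, the last at least 29.1-fold without RMF 1. Kap, Krt19 and Mup20 stood at 11.5 ± 5.68, 3.70 ± 1.44 and 7.46 ± 3.38 CPM, with WT counts of Kap in WT 4, of Krt19 in WT 3 and of Mup20 in WT 1 alone. Lamr1-ps1 stood at 9.99 ± 2.16 CPM. Among skeletal muscle genes Atp2a1 fell from 11.3 to 0.34 CPM, Myh4 from 16.4 to 0.305, Acta1 from 11.5 to 3.38 and Ckm from 5.08 to 0.0792. Tnnt3 fell from 5.97 to 0.0791, Tnni2 from 2.29 to 0.386, Actn3 from 3.84 to 0.819, Myl1 from 2.55 to 0.526 and Tnnc2 from 1.79 to 0.0507 CPM. Without RMF 4 the RMF mean of Myh4 was 0.140 CPM, and without RMF 1 that of Tnnc2 was 0.0141. Gstp2, a glutathione transferase gene with near-identical relatives, fell to 0.440-fold and Slc30a3 to 0.742-fold. Of the 160 genes higher in RMF, 31 were on an organ list, written after the calls were seen. On the 7 microglia, complement, antigen presentation, lysosome and cytokine lists, fixed with the design, were 39.

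In all, edgeR called 172 of 14428 genes in RMF against WT, 160 higher and 12 lower, with 142 and 11 differing by at least 1.5-fold. An unadjusted p below 0.05 was found for 1212 genes, where chance gives 721, and the groups did not overlap for 6.75% of genes, where chance gives 2.86%. Of the 47 lists 19 passed with the preset correlation, 7 of them with an estimated correlation and 15 of them by fry. By fry the list of amyloid processing and clearance also passed, upward (adjusted p = 0.0435 by fry, against 0.101 by camera). The number of genes was 112 with the replicate number as a block, 121 without genes on the organ lists (40 removed, and 11 that lost their call when the same p-values were adjusted over the rest), 121 without RMF 2, 141 with only the compared groups fitted, 260 without WT 3 and sham 4, 308 with library weights, 315 by DESeq2, 354 without a filter on low values and 378 with a minimum FPKM of 0.1. Leaving out 1 library ended the calls of H2-D1, Prdx6, Gfap, Sqle, Ncf1, Gstp2, Lgals3, Trim30a, Cybb, Cyba, Slc30a3, Osmr, Cx3cr1 and Tnnc2. The calls of H2-D1 and Prdx6 ended in 10 of the 11 fits that left out 1 library, with adjusted p reaching 0.12 and 0.157 without WT 4, and that of Gfap in 8, reaching 0.105 without RMF 2.

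In no comparison did 23 of the 47 lists pass by camera with the preset correlation, and the lowest adjusted p among them by that test was 0.0597. Of the 23, fry called autophagy in sham against WT and amyloid processing and clearance in RMF against WT. The 23 were 9 pathway lists, namely autophagy, amyloid processing and clearance, tau and its kinases, GABAergic genes, neurotrophin and neurogenesis genes, mitochondrial dynamics and mitophagy, iron handling, the circadian clock and apoptosis. The others were 14 marker lists, namely neurons, dentate granule cells, CA1 and CA2 and CA3 pyramidal cells, endothelial cells, fibroblasts and meninges, choroid plexus, ependymal cells, red blood cells, T and B cells, thalamus and habenula, striatum, neocortex and sex-linked genes.

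The last comparison asks whether genes that differed between sham and WT moved back with the field. Since 0 genes passed in RMF against sham by edgeR, 0 genes passed in both comparisons with opposite signs. DESeq2 gave 3, namely Ndufa2, Ankrd29 and the pseudogene Gm12751, of which Gm12751 was chosen after its values were seen. Ppia was the 1 such gene by edgeR without sham 1, with log2 differences of -1.64 for sham against WT and 1.51 for RMF against sham. In sham 3 and sham 4, where Ppia stood at 140 and 162 CPM, the pseudogene Gm10123 stood at 271.5 and 224 CPM. It was also chosen after its values were seen, and it stood at 20.1 to 117 CPM in the other libraries. Pseudogene values are uncertain here, so Ppia is not read as a gene that moved back. Of the 122 genes higher in sham, 105 were also called higher in RMF against WT, where independent lists would share 1.35. Of the 12 lower, 11 were also called lower, where independent lists would share 0.00998. A simulation with all 11 libraries drawn at equal means shared 0 called genes. With no difference between groups almost no gene is called, so it does not show what the shared WT libraries add. The median log2 difference of the 122 genes from WT was 1.81 in sham and 1.82 in RMF, and that of the 12 genes was -2.96 and -2.44.

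Both comparisons with WT use the same WT libraries, and sham libraries enter sham against WT and RMF against sham with opposite signs. Across genes, which are not independent replicates, the log2 differences of sham from WT and of RMF from WT correlated at 0.857, against 0.464 in simulated unchanged groups, with a covariance of 0.198 against 0.0307. With separate WT libraries in each comparison the correlation averaged 0.561 (0.508 to 0.647 over 6 assignments) and the covariance 0.153. The differences of sham from WT and of RMF from sham correlated at -0.408, against -0.573 in unchanged groups, with a covariance of -0.0532 against -0.041 (-0.0442 to -0.0358 over 20 simulations). Of the 122 genes, 65.6% lay lower in RMF than in sham, with a median log2 difference of -0.09. When sham and RMF were simulated as equal the share was 64% (60.3% to 66.2% over 10 simulations) and the median -0.10.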

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

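The tests of the organ transcripts, of the length trend in the 7 lists that separated RMF from sham, of sham 4 alone, of the dissection of WT 3 and of the splits of RMF against sham by genes past the threshold were chosen only after those results were seen.

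A library was singled out when its gap to the nearest library of its group was large beside the range of the group. Of 102 checks of library measures and list scores 6 met this, and of 230 checks of single genes 18 did, where chance gives about 5% of checks. The 5% does not apply to genes with counts in only 1 library of a group, which always meet it. Among the 18 these were Kap, Krt19, Zg16 and Mup20 in WT. These checks covered the groups of 4 libraries, WT and RMF, and the 3 sham libraries were not checked. WT 3 accounted for 11 of the 24 values, among them Krt19 with 4 counts.

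In WT 3 the score for antigen presentation was 0.216 against -0.697 to -0.616 in the other WT libraries, that for calcium handling -0.367 against 0.05 to 0.12, that for CA2 and CA3 pyramidal cells -1.79 against 0.06 to 0.36 and that for endothelial cells 0.373 against -0.17 to -0.09. In the same library Nr4a1 stood at 505.3 CPM against 112 to 145, Btg2 at 70.29 against 21.6 to 25.1, the neuropeptide gene Npy at 37.19 against 18.91 to 19.96, Cst7 at 1.21 against 0.174 to 0.287, C1qa at 28.69 against 33.0 to 33.8 and Bag3 at 7.191 against 8.48 to 8.71. Krt19 stood at 0.05696 CPM in WT 3 and at 0 in the other WT libraries.

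The position of WT 3 was weighed first. A trend of values with transcript length is argued against, since its dentate granule cell score was -1.64 before and -1.61 after that trend was removed, below the lowest other library at -0.17. A dissected piece with less hippocampus proper and more neocortex is a candidate explanation, since WT 3 was the extreme of the 11 libraries in the direction this needs for 4 of 4 region lists (dentate, CA1, CA2 with CA3, and neocortex). No biological explanation was tested.

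In other libraries, RMF 4 had 13925 genes at an FPKM of at least 1, against 13759 to 13786 in the other RMF libraries, and RMF 2 had a thalamus and habenula score of -0.0852, against 0.13 to 0.14. RMF 3 was highest in its group for Prnp, at 1554 CPM against 1473 to 1481, and for Myl1, at 0.7483 against 0.443 to 0.462. RMF 1 was lowest for Lgals3, at 2.13 CPM against 3.93 to 4.15, and for Ncf1, at 12.03 against 16.9 to 17.3, and highest for Vim, at 60.32 against 43.7 to 45.8, and for Alb, at 109.5 against 54.7 to 58.3. Kap stood at 20.01 CPM in RMF 2 against 8.10 to 9.46, and at 0.05748 in WT 4 with 0 in the other WT libraries. WT 1 held Zg16 at 0.07259 and Mup20 at 0.1742 CPM, with 0 in the other WT libraries, and Myh4 at 9.886 CPM against 17.9 to 19.3.

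Transcripts of other organs that split by genotype were weighed next. RNA or reads of other organs entering libraries that were handled together is a candidate explanation, since members of the liver, large intestine, kidney and lung lists that had not been called followed the called ones: 66.7% of them (16 of 24) were higher in every APP/PS1 library than in every WT library, against 2.68% of all genes with at least 20 counts and 0.303% by chance. Alb, the most abundant gene of the 4 organ lists, reached 219 CPM in sham 1. It was called in sham against WT, so it is not among the 24 uncalled members. Higher expression in hippocampal cells of APP/PS1 mice stays open, and here it cannot be told apart from handling by genotype, with 12 of 16 skeletal muscle genes higher in every WT library than in every APP/PS1 library. C3, the smooth muscle genes and other genes that these organs and the brain both express are open to the same question.

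The lists that separated RMF from sham were weighed last, with a trend of values with transcript length tested on log2 CPM values, where 6 of the 7 lists passed before the trend was removed and 3 after. Length is argued against as the whole cause for oxidative phosphorylation genes, which kept 65.5% of their median log2 difference (0.25 before, 0.17 after, with an SD of the sham scores of 0.20 and 0.16, adjusted p = 4.43e-08, and adjusted p = 0.905 with an estimated correlation), and for presynaptic genes, which kept 99.8% (-0.12 before and after, SD 0.05 and 0.03, adjusted p = 0.0268, and adjusted p = 0.905 with an estimated correlation). Length is a candidate explanation for calcium handling genes, which kept 32.6% (-0.12 before, -0.04 after, SD 0.06 and 0.12, adjusted p from 0.0226 to 0.511), and it cannot be told apart from the field where the call ended as the mean shrank, namely for postsynaptic genes (85.3% of the median kept, mean from -0.12 to -0.07, SD 0.10 and 0.15, adjusted p from 0.022 to 0.302) and plaque-associated microglial genes (83.3%, mean from 0.20 to 0.16, SD 0.23 before and after, adjusted p from 0.022 to 0.0762), where there was no call before (oxidative stress genes, 108%, adjusted p from 0.0617 to 0.216), or where the median stayed within the SD of the sham scores (mitochondrially encoded genes, 125%, -0.38 after with an SD of 0.52, adjusted p = 0.00285). Sham 4 alone is argued against as the whole cause for the 5 of the 7 lists that kept their call and direction without it, although the score difference of oxidative phosphorylation genes went from 0.25 to 0.13, and it stays open for the mitochondrially encoded and oxidative stress lists (adjusted p = 0.722 and 0.173 without it). Chance stays open, since 17 of the 35 splits of these 7 libraries gave at least the 7 lists of the real split, with up to 18 in another split, and an effect of the field stays open.

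Other splits of the same libraries were counted for the remaining results. In sham against WT only the real split, 1 of 35, gave as many as 134 genes, with at most 1 in another. In RMF against WT only the real split, 1 of 35, gave as many as 172, with at most 2 in another. Chance is argued against for both counts but not excluded, since 1 of 35 is the smallest share that the real split can give. In RMF against sham the real count was 0, which all 35 splits reach by definition, with at most 1 in another, so that count decides nothing. There 2 of 35 gave at least the real 994 genes at an unadjusted p below 0.05, with 1062 in the split that set sham 1 with RMF 2, RMF 3 and RMF 4, so chance cannot be excluded. At the same cut-off, splits of sham against WT gave up to 2322 genes, against 1907 in the real split, so chance cannot be excluded for that count either. For the number of lists, 10 of 35 splits gave at least the 16 of sham against WT, with up to 26, and 12 of 35 at least the 19 of RMF against WT, with up to 25, so chance cannot be excluded for the number of lists alone.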

How the results depend on the processing

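DESeq2, limma on log2(FPKM + 1), the removal of organ genes, the removal of WT 3 with sham 4 and library totals alone were chosen after seeing the data. Sex as a covariate was not run, since all libraries held Y-linked transcripts. Of 145 called results of named genes, 88 kept their call in up to 27 alternatives, and of all values of single genes under an alternative 8730 were counted as unchanged, 415 lost the call and 104 gained it. For a gene not called in the main fit, a value with the other sign was also counted as unchanged. For sham against WT, 134 genes became 304 without a filter, 363 at a minimum FPKM of 0.1, 345 with DESeq2, 252 with library weights, 215 at an adjusted p below 0.1, 76 with the compared groups alone and 71 without organ genes, as 46 called genes were removed and 17 lost their call when the same p-values were adjusted over the remaining genes, and 89 to 153 with 1 library left out. For RMF against WT, 172 became 354, 378, 315 and 308 under the first 4 of these settings, 260 without WT 3 and sham 4, and 121 to 203 with 1 library left out. For RMF against sham, 0 became 16 with DESeq2 and 0 to 1 with 1 library left out, and genes with opposite signs became 3 with DESeq2 and 0 to 1. Lists past the threshold fell from 16 to 6 and from 19 to 7 against WT with an estimated correlation, and lay between 14 and 17 and between 17 and 23 with 1 library left out. For RMF against sham 7 lists became 0 with an estimated correlation, 0 by fry, 4 with library weights and 3 to 13 with 1 library left out. The immediate early list reversed in sham against WT without WT 3 and sham 4 (adjusted p = 0.783), as did the mitochondrially encoded list in RMF against sham without sham 4 (0.722, against 1.93e-07 without sham 1) and without WT 3 and sham 4 (0.662). Apart from the removal of organ genes, the cause was not tested.

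Same-numbered libraries did not deviate together, with correlations from -0.246 to 0.156, 1 of 10 pairs over 0.1 and 1 of 11 libraries best matched by its own number, so the numbers do not pair the libraries. With the replicate number as a block, the counts were 87 genes for sham against WT and 112 for RMF against WT. Depth was even, and at 3 or 4 libraries a group a 1.5-fold change was recovered in 21% of simulated genes in RMF against sham.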

Other observations

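The genes in this part were chosen only after their values were seen, and no test beyond the comparisons above was run on them.

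Genes outside the fixed lists that passed in both comparisons with WT included those that follow. Mpeg1, which encodes the pore-forming protein perforin-2 of macrophages, rose from 33.8 ± 2.63 CPM in WT (SD, n = 4) to 83.2 ± 14.0 in sham (n = 3) and 84.96 ± 7.62 in RMF (n = 4), 2.46- and 2.51-fold (edgeR adjusted p = 0.000147 and 0.000122). Cd84, a receptor of immune cells, rose 2.63- and 2.47-fold, Csf3r, the receptor of granulocyte colony-stimulating factor, 2.09- and 2.20-fold, and Lag3, an immune checkpoint receptor gene, 2.23- and 1.89-fold. Plin2, which coats lipid droplets, rose 1.92- and 1.81-fold from 3.87 ± 0.618 CPM. Sgk1, a glucocorticoid-induced kinase gene, rose 1.87- and 2.21-fold from 59.7 ± 12.3 CPM, and Tent5c, a poly(A) polymerase gene, 3.11- and 3.19-fold. The call of Sgk1 in sham against WT ended in 8 of the 11 fits that left out 1 library, with adjusted p reaching 0.147 without sham 3. That of Lag3 in RMF against WT ended in 5 of 11, reaching 0.0779 without WT 4.

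Ppia stood at 140 and 162 CPM in sham 3 and sham 4, against 362 to 495 in the other 9 libraries, and Gm10123, which the table lists as a processed pseudogene, stood at 271.5 and 224 CPM in those libraries, against 20.1 to 117 in the others.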
